A study of Neurospora crassa with 16 samples.

How the data were processed

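The series measured DNA methylation by bisulfite sequencing, histone marks by chromatin immunoprecipitation with sequencing (ChIP-seq) and polyadenylated RNA by RNA-seq in Neurospora crassa, a filamentous fungus. Its 16 samples fall into groups by strain and assay, per the labels. Per the labels, the RNA came from cultures of germinated conidia, the asexual spores, shaken for 16 h at 32 °C in Vogel's minimal medium with 1.5% sucrose. The libraries were made with a stranded mRNA kit, per the labels' protocols. The files used here are the count files of the 2 Δlsd1 RNA-seq libraries, the authors' 2 deposited tables of genes called higher and lower in Δlsd1, and a deposited list of genomic regions. The other 14 samples have no file of their own here and were not analysed here.

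The deposited count files hold a raw read count for each of 9730 genes, not normalised. Alignment used Bowtie2, per the submitters' processing notes, which also name DESeq2 and deepTools. Versions, the genome build of the alignment and the counting program are not given in the sources used here, nor whether counting used strand. The files close with rows that name no gene, and these stayed out of library sizes and tests. In these deposited closing rows, reads outside any gene made up 12.3% of all counted reads in replicate 1 and 12.7% in replicate 2, reads aligned to more than 1 place 3.74% and 3.38%, and ambiguous reads 0.117% and 0.0879%.

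The authors' deposited tables give, per the file headers, a mean normalised count over all libraries and in each group, the fold change as a ratio, its log2, a p-value and an adjusted p-value. The comparison was with 2 wild-type libraries of another series, per the series' design text; their counts were not used here, so no count model across groups was fitted. The column names are those of the older DESeq package, while the submitters' processing notes name DESeq2, so the program behind the p-values is open. The direction of the tables was settled from the values. The Δlsd1 mean of all 1060 tabled genes was recovered, with a largest relative error of 5.11e-15, as the mean over both Δlsd1 libraries of the count plus 1 divided by a size factor of 0.640 for replicate 1 and 0.591 for replicate 2. Without the added 1 the median error was 2.37%, and with the groups exchanged it was 81.5%. A positive log2 fold change in the authors' deposited tables therefore means a higher level in Δlsd1, and the added 1 shrinks the fold changes of genes near 0 reads. The tables hold genes that changed at least 2-fold, with an unadjusted p-value of at most 0.0497 and an adjusted p-value of up to 0.170. A gene is called higher or lower below when it is in these tables.

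The region list holds the start and end, a pair of positions (unit other), of 250 deposited regions, with no header and no score. How they were called, and on which samples, is not given in the sources used here. Their sequence names are those of the Neurospora assembly NC12, the assembly of the reference gene table, whose chromosomes I to VII were matched to supercontigs 1 to 7. Of the 5040 possible assignments, 2 fit the extents within 10000 bp, and the assignment by number was among them. Coordinates are 1-based on NC12. The reference table matched 9729 of the 9730 counted identifiers, and 1118 of its 10590 genes carry a symbol. It gives no product names and came without the genome sequence, so 18 gene lists defined by product name and a test of base composition of the regions were not run. Adjustment over the list alone was not possible for the gene lists, because the authors' deposited tables give a p-value only for the genes they hold.

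The analysis used R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The samples' groups, the main tests, alternatives to them, 10 gene lists by locus and the rule for named genes were fixed before the data were examined. The tests of the regions' gene body share, of the gaps between regions, of the number of overlapped genes and of lower against higher genes in the regions were added afterwards. The rule names lsd1 and its neighbours, and in each direction the 5 genes with the largest absolute log2 fold change and the 8 with the largest that carry a symbol, at a mean of at least 50. It also takes up to 4 members of each list, the 5 genes with the largest change that overlap a region in each direction, the 5 highest genes of the count files and the 5 that differ most between the libraries. Another 13 lists of symbol families were written after the files were seen and before the calls of their genes were seen.

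The counts of both Δlsd1 libraries were scaled with edgeR's trimmed mean of M values (TMM), over genes with at least 10 counts in each library. Their spread was estimated as edgeR's common dispersion, given as the biological coefficient of variation. Each gene's split between the libraries was tested with an exact binomial test, with Benjamini-Hochberg adjustment at 0.05; this compares libraries, not conditions. Gene lists with at least 5 background members were tested with Fisher's exact test, two-sided, against the genes with at least 1 count, with Benjamini-Hochberg adjustment within the fixed and within the added lists. Overlap of genes with regions was set against 10000 circular shifts of all regions along the chromosomes, and levels were log2 of the mean CPM, the count scaled to its library's total on genes, plus a pseudocount of 0.5. Genes within 200 kb of a chromosome end, bounded by the last gene or region, were tested with Fisher's exact test and by 10000 circular shifts of the calls along the gene order. Neighbouring pairs of called genes were set against 10000 shuffles of the calls, one-sided. The smallest p-value is 0.0001 for these one-sided tests and 0.00020 for the two-sided ones.

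The tests were tried on simulated data. A simulated variation of 20% between the 2 libraries was recovered as 19.9% over 7319 genes. The split test called 91% of genes changed 2-fold, all of those changed 4-fold and 0.140% of unchanged genes, with counting noise alone. With regions placed at random over 9729 genes, the shifts of the regions called 4% of 200 runs. With regions kept in place and calls unrelated to them, this test called 30% of 100 runs, Fisher's exact test 5% and shifts of the calls along the gene order 3%. When overlapping genes were made 2 times as likely to be called, these shares were 33%, 90% and 89%. Fisher's exact test of chromosome ends called 8% of 100 runs with no link over 8687 genes.

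The libraries hold 7017726 and 6797672 counts on genes, and a count of 0 allows a level of up to 0.427 CPM in replicate 1 and 0.441 CPM in replicate 2, the level of 3 counts. Intervals are exact 95% binomial intervals for shares, and these floors and intervals cover counting error only. The labels number the 2 libraries as replicates and do not say whether they come from separate cultures. The p-values between them measure only departure from counting noise in these samples, not a spread between cultures. The Δlsd1 strain is labelled mating type a and the wild type mating type A, so strain background and the deletion are not separated in any comparison with wild type. The wild-type libraries also belong to another series, so differences between the series are not separated from the deletion either. Alternatives were other scalings, count minimums, backgrounds, thresholds, overlap rules and distances, and leaving out each replicate.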

Results

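The study asked what the loss of lysine-specific demethylase 1 (LSD1), a histone demethylase encoded by lsd1, does to heterochromatin and gene expression in Neurospora crassa. Expression was measured in Δlsd1 strain N5555, in which lsd1 is replaced by the hygromycin resistance marker hph, as 2 RNA-seq libraries. The wild-type reference enters through the authors' 2 deposited tables of genes called higher or lower. Replicate 1 held 7017726 reads on genes and replicate 2 held 6797672. Of 9730 counted genes, 7319 had at least 10 reads in both libraries, 8688 had at least 1 read in either, and 1042 had none.

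The targeted gene and the mating type genes were read first, as a check of the labels. NCU09120 (chromosome I, 5405126 to 5410394), which has no symbol in the reference table and is taken as lsd1 from knowledge of the gene, had 41 reads in replicate 1 and 65 in replicate 2, a level of 7.70 ± 2.63 CPM (SD, n = 2). The authors' deposited table of lower genes gave lsd1 a normalised mean of 675 in wild type and 88.7 in Δlsd1, a log2 fold change of -2.93 (adjusted p = 7.06e-15). The gene was thus much reduced but not at 0, and which part of it was replaced is not given in the sources used here. Its neighbours were in neither table, and stood at 392 ± 29.0 CPM (NCU09119, SD, n = 2) and 159 ± 11.2 CPM (NCU09121, SD, n = 2). The annotated span of NCU09121 starts at 5410375, inside the end of lsd1, where reads cannot be told apart without strand. The mating type genes matA-1, matA-2 and matA-3 and the mating type A pheromone precursor gene ccg-4 had 0 reads in both libraries, as did 1042 genes in all. For matA-1 the level in Δlsd1 lay at least 9.50-fold lower by the wild-type mean of the authors' deposited table, which gave an adjusted p = 0.00335. This fold set that mean, lowered by 2.02, the lowest wild-type mean of any tabled gene, against a floor of 3 counts over both libraries. The pheromone precursor gene of mating type a, mfa-1, had a log2 fold change of 1.18 in the authors' deposited table with an adjusted p = 0.0642.

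The most abundant transcripts of both Δlsd1 libraries came from ccg-14, a clock-controlled gene, at 42199 ± 7222 CPM (SD, n = 2), and gpd-1, glyceraldehyde-3-phosphate dehydrogenase, at 23871 ± 2147 CPM (SD, n = 2). They were followed by NCU00399, ccg-13 and NCU05395, and none of these 5 was in the authors' deposited tables. The 10 highest genes took 17.6% of reads in replicate 1 and 19.8% in replicate 2. Across genes, which are not independent replicates, the log2 levels of the libraries had a Pearson correlation of 0.985. The biological coefficient of variation was 15.3%, and the counts differed by more than sampling noise (chi-square of 166730 over 7319 genes). By the exact binomial test, 1949 genes (26.6%) differed between the libraries, 951 of them higher in replicate 1 and 998 in replicate 2. Over all 7319 genes, with or without passing that test, 172 differed at least 2-fold. The largest difference was at mig-2, with 135 reads in replicate 1 and 11 in replicate 2, followed by NCU08413 with 602 and 3662 reads. The next were NCU00607 (59 and 312 reads), NCU16445 (49 and 232) and NCU00732 (74 and 343), all of them called lower in Δlsd1.

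Loss of lsd1 was accompanied by more genes called lower than higher, 755 against 305 in the authors' deposited tables. Among genes with a symbol and a normalised mean of at least 50 over both strains, the largest decreases in the authors' deposited table were at aln-1, allantoinase of purine breakdown, with a log2 fold change of -3.03, inl, myo-inositol-1-phosphate synthase (-2.43), gcy-1 (-2.34) and arg-13, the mitochondrial ornithine carrier (-2.33). Next in the authors' deposited table stood cel-2, a fatty acid synthase subunit (-2.31), the polygalacturonase gene gh28-1 (-2.23), pyr-3 of pyrimidine synthesis (-2.21) and the MutS homologue msh4 (-2.21). Each of these 8 had an adjusted p of at most 2.30e-06 in the authors' deposited table. Against the wild-type mean of the authors' deposited table, gh28-1 stood at -3.41 on the log2 scale with replicate 1 alone and -1.59 with replicate 2 alone, and pyr-3 at -2.85 and -1.77. The largest increases with a symbol at the same minimum in the authors' deposited table were mig-4 at a log2 fold change of 2.19, whose adjusted p was 0.0594, then gh61-6, a polysaccharide monooxygenase gene (1.88), the kinase gene stk-8 (1.67), and nca-3, a calcium ATPase gene (1.55). They were followed in the authors' deposited table by the blue light-induced gene bli-4 (1.49), the glucoamylase gene gla-1 (1.48), the chromatin gene chap (1.48), and the conidiation gene con-6 (1.41), whose adjusted p was 0.162.

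Several genes without a symbol changed more. At the same minimum, the largest increases in the authors' deposited table were at NCU07822 on chromosome III, with a log2 fold change of 3.63, NCU08271 (3.03), NCU04407 (2.63), NCU07497 (2.54) and NCU07938 (2.53). The largest decrease was at NCU09968 (chromosome VI, 309546 to 315476), which had 0 reads in both Δlsd1 libraries. Its wild-type mean was 1299 in the authors' deposited table. Lowered as for matA-1, that mean put the level in Δlsd1 at least 532-fold lower against a floor of 3 counts over both libraries. NCU05122 kept 3 reads, 256-fold lower by the wild-type mean of the authors' deposited table with a counting interval of 87.6 to 1241. NCU05788 had a normalised mean of 9.96 against 755 in wild type in the authors' deposited table, a log2 fold change of -6.24. With replicate 1 alone (2 reads) this value was -7.33 and with replicate 2 alone (8 reads) -5.63, against the wild-type mean of the authors' deposited table. NCU09964 had 1 read and lay 209-fold lower (37.4 to 8240), and NCU02919 had 2 reads and lay 70.7-fold lower (19.6 to 584), both by the wild-type means of the authors' deposited table. All of these reads came from replicate 2, and both genes had 0 reads in replicate 1. The folds of NCU05122, NCU09964 and NCU02919 use the wild-type mean as given and leave out the 1 that the authors' deposited table adds to each Δlsd1 count. That table gave them log2 fold changes of -7.25, -6.10 and -5.11, placing NCU09964 behind NCU05788.

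**Figure D1:**
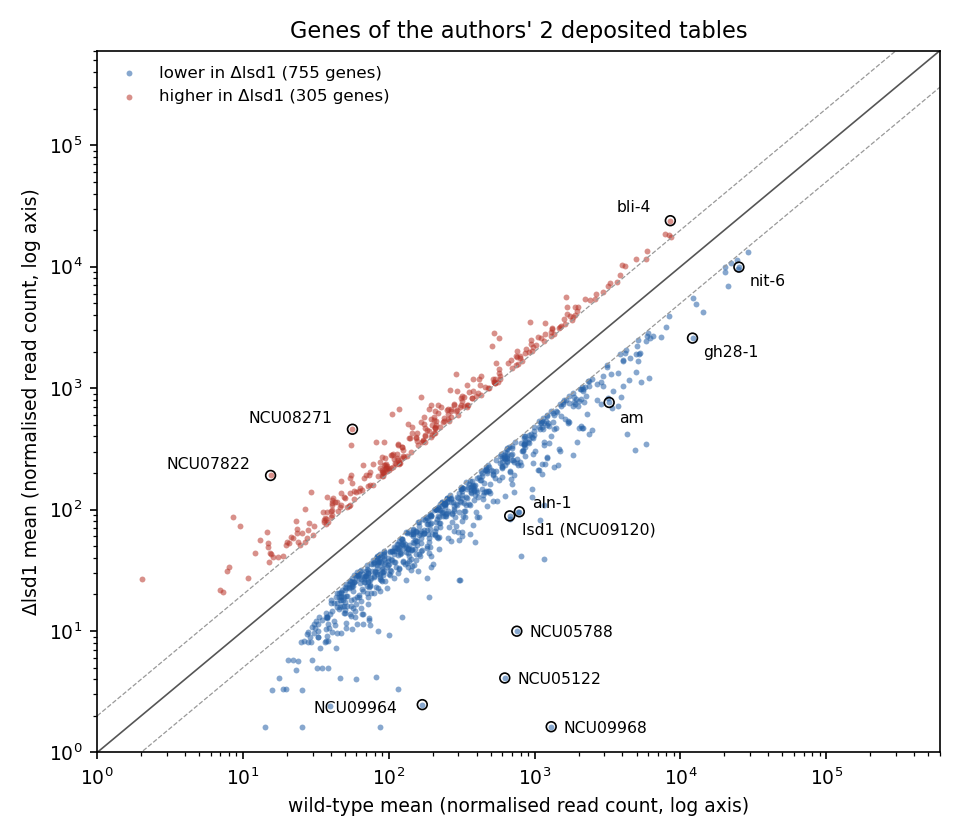
Mean normalised read count in wild type (horizontal, log axis) and Δlsd1 (vertical, log axis) of the 755 genes called lower (blue) and the 305 called higher (red) in the authors' deposited tables; the solid line marks equal levels and the dashed lines a 2-fold change. NCU09968, at a wild-type mean of 1299, lies lowest against its wild-type level, and lsd1 lies at 675 in wild type and 88.7 in Δlsd1.

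Most changes were small. The median log2 fold change in the authors' deposited tables was 1.25 for higher and -1.41 for lower genes, and 18 higher and 127 lower genes changed at least 4-fold. An exact two-sided binomial test of 755 lower against 305 higher genes gave p = 1.34e-44, over genes that are not independent. The strains compared also differ in mating type, and their libraries belong to different series. The authors' deposited tables hold 148 genes with an adjusted p of 0.05 or more; 273 higher and 639 lower genes lie under 0.05. Against the authors' wild-type mean, 222 higher and 558 lower genes changed at least 2-fold in each Δlsd1 library taken alone.

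No list of chromatin functions passed Fisher's exact test for called members (unadjusted p from 0.349 to 1), and the housekeeping genes were too few to test. These lists are small, so the test could hardly tell no called member from the share among other genes. For the 6 histone genes that share was 3.51% higher and 8.65% lower, and the odds ratio intervals reached 23.4 and 8.99. Of 12 genes for DNA methylation and histone H3 lysine 9 methylation, among them dim-2, the DNA methyltransferase, and dim-5, the H3K9 methyltransferase, 1 was called, chap, a member of the HDA-1 deacetylase complex; the authors' deposited table gave it a log2 fold change of 1.48 (adjusted p = 2.18e-06). None of 8 other histone methyltransferase and Polycomb genes, 6 histone genes, 7 clock and light response genes, 7 quinate genes or 4 housekeeping genes was called. Of 9 RNA silencing and RIP genes, the authors' deposited tables held rid-1, required for repeat-induced point mutation, at 1.13 on the log2 scale (adjusted p = 0.0452) and qde-1, the RNA-dependent RNA polymerase of quelling, at -1.03 (adjusted p = 0.00283). Of 11 conidiation and carotenoid genes, con-10 fell (log2 fold change -1.75) and csp-2 rose (1.05) in the authors' deposited tables, and con-6 had an adjusted p = 0.162.

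Genes of carbon and nitrogen metabolism gave the largest share of called members among the fixed lists that were tested. In the authors' deposited table am, glutamate dehydrogenase, had a log2 fold change of -2.09, nit-3, nitrate reductase, -1.71, nit-6, nitrite reductase, -1.34, and cre-1, the carbon catabolite repressor, -1.43, while gla-1 stood at 1.48. These 4 lower genes were 30.8% of 13 members, against 8.61% of 8675 other background genes, with an odds ratio of 4.72 (1.06 to 16.9), a two-sided Fisher's exact p = 0.0210 and an adjusted p = 0.337. Over the 16 tests of fixed lists, 0 passed Fisher's exact test after adjustment and 1 had an unadjusted p under 0.05.

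Among the 13 symbol families, 4 of 10 heat shock genes and 10 of 60 amino acid synthesis genes were called lower. In the authors' deposited table the heat shock genes were hsp80 (log2 fold change -1.46), hsp88 (-1.28), hsp60 (-1.25) and hsp70-5 (-1.05). The amino acid genes with the largest decreases in the authors' deposited table were arg-13 (-2.33), ilv-6 (-1.97), leu-2 (-1.72) and arg-3 (-1.44), while arg-14 was called higher (1.26). Fisher's exact test gave odds ratios of 7.08 (1.47 to 29.9, adjusted p = 0.198) for the heat shock genes and 2.13 (0.958 to 4.27, adjusted p = 0.467) for the amino acid genes. Of 79 glycoside hydrolase genes 8 were called lower and 1 higher, of 53 stk kinase genes 4 and 2, of 34 DNA repair genes 2 and 1, and of 28 cell wall genes 1 and 2. Of 16 acetyltransferase and deacetylase genes 1 was called lower, nst-6. None of 29 complex I, 30 proteasome, 20 peroxin, 13 vacuolar ATPase, 21 mitochondrial import or 9 cell fusion genes was called. Over the 26 tests of these families, 0 passed Fisher's exact test after adjustment and 2 had an unadjusted p under 0.05.

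**Figure D2:**
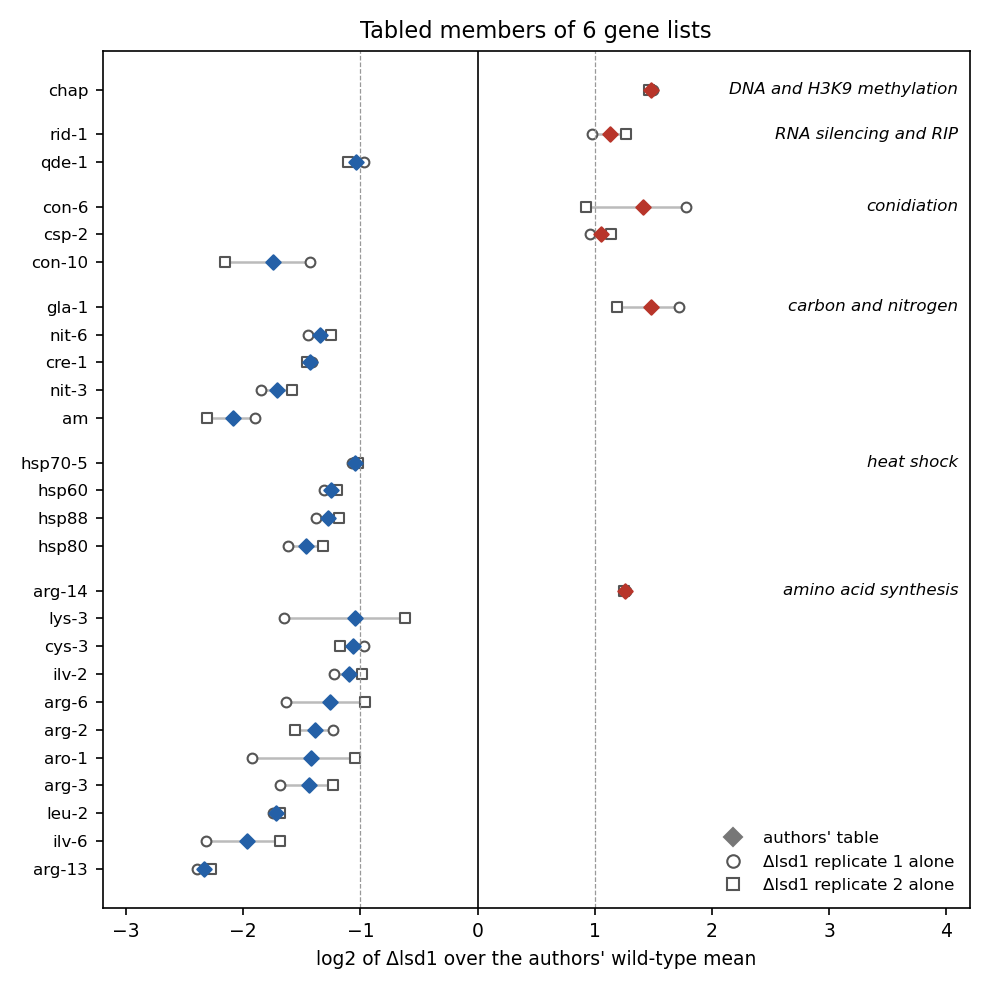
Log2 of the Δlsd1 level over the authors' wild-type mean (horizontal) for the called members of 6 gene lists (vertical), as the authors' deposited tables give it (diamonds, red higher, blue lower) and with Δlsd1 replicate 1 (circles) or replicate 2 (squares) alone; dashed lines mark a 2-fold change. Both libraries lie on the same side of 0 for every gene shown, from arg-13 at -2.33 to gla-1 at 1.48.

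The deposited regions were many, short and scattered over all 7 chromosomes. The 250 regions covered 785 kb, 1.95% of the chromosomes' extent, with a median length of 2171 bp and a range of 123 to 18082 bp. Chromosome I held the most, 61 regions, and chromosome VII the most per length, 8.26 per Mb, against 4.55 per Mb on chromosome III. The longest (chromosome IV, 5569365 to 5587446) overlapped NCU05259, NCU05257, NCU05256 and NCU05255, and the fifth longest (chromosome IV, 4417853 to 4431649) overlapped the whole of the fatty acid synthase gene cel-1 and 0.605% of cel-2. In all, 152 regions overlapped a gene and 98 lay between genes, and 236 genes were overlapped. Gene bodies made up 45.1% of the regions' length, less than the 56.8% (51.5 to 62.0) found over 10000 circular shifts (permutation p = 0.0004), in a test added after the data were seen. Regions also lay near each other in another added test, with 59 of 243 gaps under 20 kb against 33.5 (24 to 44) for regions placed at random (permutation p = 0.00020, the smallest it can give).

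**Figure D3:**
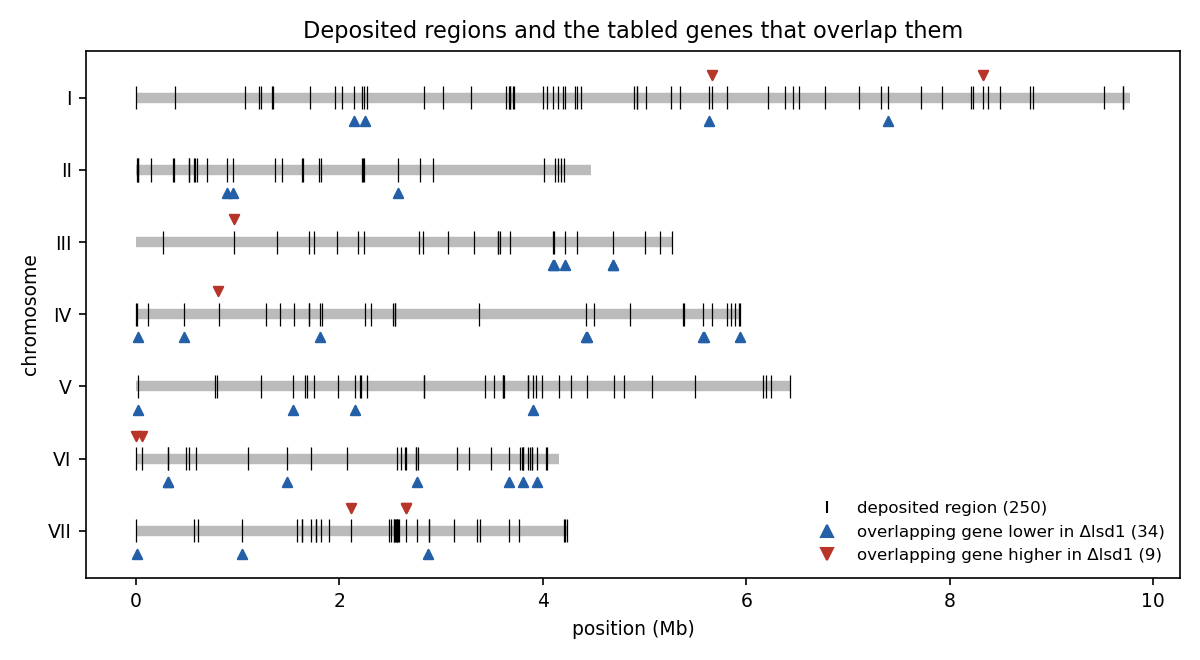
Position in Mb (horizontal) of the 250 deposited regions (black ticks) on chromosomes I to VII (grey bars, vertical) of assembly NC12, with the 34 overlapping genes called lower in Δlsd1 (blue triangles under the bar) and the 9 called higher (red triangles above it). The regions spread over every chromosome, 61 of them on chromosome I.

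Genes called lower overlapped a region in 34 of 755 cases, and among them was NCU09968, the most strongly reduced gene of the authors' deposited table. NCU09969 (chromosome VI, 314113 to 320071), also with 0 reads in both libraries, lay at least 35.1-fold lower. This fold set its wild-type mean in the authors' deposited table, lowered as for matA-1, against the same floor of 3 counts. NCU09969 shares 314113 to 315476 with NCU09968, where reads cannot be told apart without strand. Next by log2 fold change in the authors' deposited table came NCU10040 (-3.36), NCU05569 (-2.84) and pks-5, a polyketide synthase gene (-2.57). Genes called higher overlapped a region in 9 of 305 cases, led in the authors' deposited table by NCU07143 at the left end of chromosome VI (log2 fold change 1.89), NCU02396 (1.58), NCU10772 (1.29, adjusted p = 0.133), NCU02458 (1.28) and NCU02395 (1.18). The share was 4.50% of lower genes (3.14 to 6.24), 2.95% of higher genes (1.36 to 5.53) and 2.23% (1.93 to 2.56) of 8669 genes in neither table, all with exact binomial intervals.

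Against circular shifts of the regions, the test fixed for this comparison, the overlap did not pass, with 27.2 lower genes (18 to 38) overlapping by chance (ratio 1.25, permutation p = 0.226) and 9.78 higher genes (4 to 17, permutation p = 0.981). That test asks about all genes at once, since shifted regions overlapped 328 genes on average against 236 observed (permutation p = 0.00020). It called 30% of simulated runs with no link and 33% with overlapping genes 2 times as likely to be called. Its outcome therefore cannot separate a link from none. Against genes in neither table, Fisher's exact test gave lower genes an odds ratio of 2.07 (1.38 to 3.02, p = 0.000429) and higher genes 1.34 (0.595 to 2.62, p = 0.427). Shifts of the calls along the gene order gave 18.2 lower genes by chance (permutation p = 0.00080). Lower and higher genes were not shown to differ from each other (odds ratio 1.55, 0.717 to 3.72, Fisher's exact p = 0.303). With overlap of at least 50% of the gene body, 23 lower genes were observed against 13.6 by shifts of the regions (permutation p = 0.0262). Within 1 kb of a gene there were 57 against 35.6 (permutation p = 0.0020). Both rest on the same shifts of the regions and neither rule was tried on simulated data, so no conclusion is drawn from them.

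**Figure D4:**
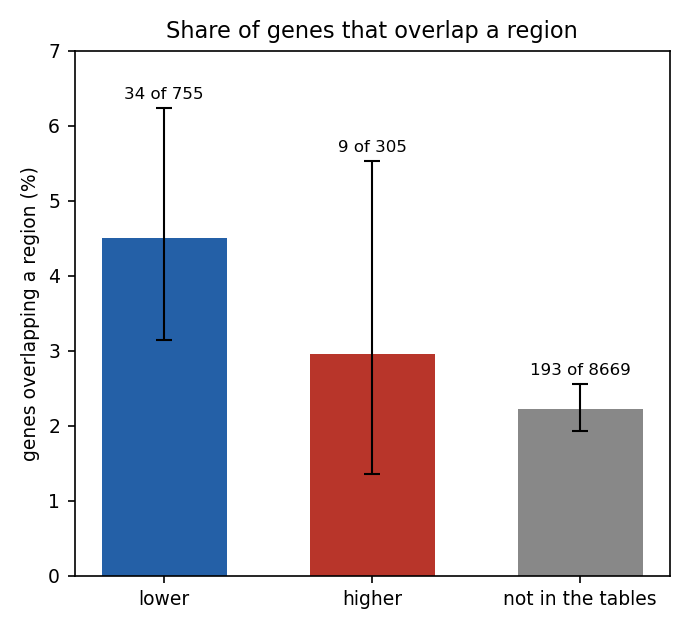
Percentage of genes that overlap a deposited region (bars, vertical axis from 0) among genes called lower, called higher and in neither table (horizontal), with exact 95% binomial intervals (lines) and counts above. The share is 4.50% for lower genes, 2.95% for higher genes and 2.23% for the others.

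Genes that overlapped a region did not stand apart in level from other genes when all were counted. Their median level was 20.7 CPM in the Δlsd1 libraries against 14.2 CPM for other genes, a difference of 0.53 on the log2 scale, within the range of -0.12 to 0.72 over circular shifts (permutation p = 0.342). Among genes with at least 10 counts in each library the medians were 46.7 and 26.3 CPM, a difference of 0.82 outside its shifts (permutation p = 0.00020, the smallest it can give). Of the 236 overlapping genes 10.6% had no read, and of the 9493 others 10.7%. These are levels in Δlsd1 only, with no wild-type value beside them.

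Genes called lower were found slightly more often near chromosome ends, without passing the test. The background was genes with at least 1 read, so lower genes with no read in Δlsd1 did not enter. Within 200 kb of an end lay 69 of 751 lower genes (9.19%) against 7.26% of other background genes, an odds ratio of 1.29 (0.980 to 1.68, Fisher's exact p = 0.0582, permutation p = 0.197 by shifts along the gene order). Higher genes lay there in 8.20% of cases (odds ratio 1.12, 0.705 to 1.70, Fisher's exact p = 0.578). Within 300 kb the odds ratio for lower genes was 1.43 (Fisher's exact p = 0.00155, permutation p = 0.0476), and for lower genes at least 2-fold down without replicate 2 it was 1.38 within 200 kb (Fisher's exact p = 0.0197, permutation p = 0.143).

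Called genes lay side by side more often than shuffled calls. Only genes with at least 1 read in the Δlsd1 libraries entered, 751 of the 755 lower genes, without NCU09968 and NCU09969. Genes counted as neighbours can thus have a gene with no read between them. Higher genes formed 33 neighbouring pairs against 10.7 by chance (5 to 17), a ratio of 3.10, and lower genes 96 pairs against 64.6 (51 to 80), a ratio of 1.49; both had a one-sided permutation p = 0.0001, the smallest it can give. The 71 runs of lower genes held 167 genes, and the 30 runs of higher genes held 63. The longest run, named after its values were seen, had 5 lower genes from NCU09903 to NCU09910 at the left end of chromosome I (9177 to 52949), with log2 fold changes from -1.89 to -1.01 in the authors' deposited table. A run of 4 lower genes, also chosen after its values were seen, began with pks-5 at the left end of chromosome IV (11075 to 31245), with log2 fold changes from -3.07 to -1.76 in the authors' deposited table. The 3 longest runs of higher genes had 3 genes each. Neighbouring genes with overlapping transcripts can share reads where counting ignores strand.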

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

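Settings chosen after the data were seen are the adjusted p under 0.05, the counts with at least 2-fold change in 1 or in each Δlsd1 library, the shifts along the gene order, the set without NCU09968 and NCU09969, the gene body share of the regions, also at 1 kb or more, and the symbol families. Of 38 alternatives for tested values, 26 kept direction and side of the threshold, as did all 15 for single gene lists; a 2-fold minimum is not counted, since it removes no gene of the tables. The coefficient of variation, 15.3%, was 15.7% with total count scaling and 15.5% with no filter on low counts. For lower genes overlapping regions, the ratio of 1.25 by shifts of the regions was 1.18 without NCU09968 and NCU09969. By the same shifts it passed the threshold at 1.70 for at least 50% of the gene body and 1.60 within 1 kb. Neither of these rules was tried on simulated data. It also passed at 1.86 with shifts along the gene order and an odds ratio of 2.07 by Fisher's exact test. For higher genes the ratio of 0.920 turned to 1.25 for at least 50% of the gene body, 1.22 with shifts along the gene order and an odds ratio of 1.34 by Fisher's exact test, and ranged from 0.743 without replicate 1 to 1.03 without replicate 2, all without passing. The level difference of 0.53 was 0.82 with at least 10 counts in each library. Near chromosome ends the odds ratio for lower genes was 1.43 within 300 kb and ranged from 1.27 without replicate 1 to 1.38 without replicate 2, where it passed Fisher's exact test, and for higher genes it turned to 0.552 within 100 kb. With either replicate left out, 252 to 275 of the tabled higher genes and 608 to 705 of the lower genes still changed at least 2-fold, without a test. The calling itself was not repeated, so these numbers cannot exceed those of the authors' deposited tables. The cause was not tested. Base composition of the regions and the 18 lists by product name were not run. No paired analysis was possible because a single group has count files. A count of 0 in 1 library allows a level of up to about 0.441 CPM.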

Other observations

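The genes named in this paragraph, the shifts along the gene order, the draws that used the wild-type mean, the tests on the genes with few reads and the tests on the conidiation genes were chosen after the results were seen. The genes of this paragraph were picked because they were called, with no list or test behind them. In the authors' deposited table gln-1, glutamine synthetase, had a log2 fold change of -1.91 (adjusted p = 1.87e-21), en(am)-2, glutamate synthase, -1.28 (adjusted p = 1.61e-08), and chol-1 -1.70. The fatty acid synthase genes cel-1 (-2.20) and cel-2 (-2.31) of the authors' deposited table lie side by side on chromosome IV, where a region covers 100% of cel-1 and 0.605% of cel-2. The authors' deposited table also gave decreases for aod-1, the alternative oxidase (-1.28), gsy-1, glycogen synthase (-1.34), and acu-6, phosphoenolpyruvate carboxykinase (-1.88). Against the wild-type mean of the authors' deposited table, acu-6 stood at -1.38 with replicate 1 alone (1218 reads) and at -2.63 with replicate 2 alone (473 reads). The authors' deposited tables gave -1.57 for ad-7, and increases for ad-8 (1.06), ad-9 (1.17), the catalase gene cat-1 (1.13) and bli-3 (1.40).

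Genes called lower overlapped a region at 2.07 times the odds of genes in neither table. The values argue against gene length as the cause, since draws matched on length gave 18.1 overlapping genes (11 to 26) against 34 observed (permutation p = 0.00080). They also argue against the side-by-side position of called genes, with 18.2 (11 to 27) over shifts along the gene order (permutation p = 0.00080). Draws matched on the Δlsd1 level gave 17.1 (10 to 25, permutation p = 0.00020) but decide nothing, since the change itself lowered that level. Draws with the wild-type mean for called genes and the Δlsd1 mean for all others also gave 17.1 (10 to 25, permutation p = 0.00020). These draws argue against expression level so measured, while the wild-type levels of those others are not in the sources used here. That the deposited regions may mark places where expression dropped in Δlsd1 is a hypothesis found and tested on the same data. The planned shift of the regions did not pass, and the sources used here do not say how the regions were called. Lower and higher genes were not shown to differ in overlap (odds ratio 1.55, 0.717 to 3.72, Fisher's exact p = 0.303). Expression level and the strain background of N5555 stay open.

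A set of 7 genes with a wild-type mean of at least 50 in the authors' deposited table kept at most 3 reads over both Δlsd1 libraries: NCU09968, NCU05122, NCU09964, NCU09969, NCU02919, NCU05852 and NCU02061. Silencing under the regions might account for NCU09968 and NCU09969, which overlap a region, but this is 28.6% of the set (3.67 to 71.0), too few genes to decide. NCU09968 and NCU09969 also overlap each other, so the interval, which treats them as independent, understates the uncertainty. A segment missing from the strain, as for the mat A genes with 0 reads, might account for genes at 0, but 5 of the 7 genes had 1 to 3 reads, which can also come from a related sequence. Silencing and strain background cannot be told apart here, because no genome sequence of N5555 and no wild-type library of mating type a was used here.

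The list of conidiation and carotenoid genes had a median log2 ratio of 0.44 between Δlsd1 replicate 1 and replicate 2 over 10 genes, against -0.21 to 0.16 for random lists of like level. Left out was acon-3 (11 and 9 reads), at a log2 ratio of 0.15, which would lower that median. Of these 10 genes, the 6 above 0 were eas, a hydrophobin gene (9721 and 2241 reads), con-6 (95 and 48), con-10 (272 and 152), ccg-1 (31962 and 19167), fl (705 and 436) and al-2 (17189 and 12803). The others, al-1 (-0.14), al-3 (-0.03), csp-1 (-0.12) and csp-2 (-0.18), lay below. The choice of scaling decides nothing here, since any factor moves the list and the random lists alike. A different developmental state of the cultures is a candidate explanation and stays open, because the genes that showed the pattern cannot also test it. Fold changes of con-6 and con-10 in the authors' deposited table rest on the mean of these libraries, and with 1 library alone con-6 had a log2 fold change of 1.78 or 0.92 and con-10 of -1.43 or -2.15.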
